A study of Bos taurus with 2 samples.

How the data were processed

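Messenger RNA of the longissimus muscle, the long muscle that runs beside the spine, was sequenced at 2 stages of life in Qinchuan cattle, a Chinese beef breed. One library came from embryos at 135 days after insemination (Emb135) and the other from adult animals at 30 months after birth (30M). Per the labels' protocols, muscle was frozen soon after slaughter, the RNA of 3 animals per stage was pooled before library construction, polyadenylated RNA was captured with oligo(dT) beads, fragmented and primed with random hexamers, and cDNA of a narrow size range was sequenced on an Illumina HiSeq 2000. Strand marking was not mentioned in the protocol, so reads of overlapping and antisense genes may be mixed.

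The authors deposited 1 table per library with 4 values per gene, under Ensembl gene identifiers. Per the file headers, the first value is the count of uniquely assigned reads, not normalized, and the genes' counts added up exactly to the total in each header, 17736812 reads for Emb135 and 19970007 for 30M. The lowest listed count was 1, so a gene missing from a table had 0 reads in that library. Per the file headers the next columns give the length of the gene model and its coverage. The authors' coverage signal was read as the percentage of the gene model with at least 1 read. A single gene per library exceeded 100, at 100.02 in Emb135 and 100.05 in 30M, which this reading does not allow, so it is not exact for every gene. Each of the 312 genes with 1 read in Emb135 and of the 265 such genes in 30M had 90 nt covered, which gives the read length. The authors' RPKM (reads scaled by the length of the gene model and by the library's total of unique reads) was recomputed from the counts, lengths and totals and differed by a relative error of at most 2.2e-14. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here. Counting only uniquely placed reads leaves near-identical paralogs undercounted by an amount that the tables do not show. The tables did not assign reads to isoforms.

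The tables pair identifiers with no gene names, and the reference gene table used here (37063 genes) holds Ensembl identifiers for 0 of its genes. The 33 gene lists fixed before the data were examined, cell type markers included, and the genes that were to be named in every case were therefore not analysed here, and genes are described by class. By the naming rule, genes were ranked by log2 ratio among those with an RPKM of at least 10 in the higher library; its condition of a gene symbol was met by no gene and was dropped. Only the first 2 identifiers in each direction are printed. One further identifier in the closing section was chosen after its values were seen.

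With 1 library per stage there is no replicate, so no test between stages was run and no p-value is given. A gene was called higher or lower in 30M by size: a ratio of at least 2-fold on the log2(RPKM + 0.5) scale, an RPKM of at least 1 in the higher library, and an exact 95% counting interval of the ratio of reads (Clopper-Pearson, conditional on the gene's total) that excluded equality. The pseudocount of 0.5 understates ratios of genes with low values. These intervals cover counting error only, with each read taken as independent. Reads amplified by PCR are not independent molecules, and variation between animals is averaged within each pool. Whether both ends of a fragment were counted as separate reads was not examined. If they were, the intervals are too narrow even for counting error, and bounds from a floor of reads are too large. The calls took a gene with 0 reads at an RPKM of 0. A floor of 3 reads per library was used only to bound the ratios of such genes. At these depths 1 read was worth an RPKM of 0.0296 in Emb135 and 0.0261 in 30M for a gene of median length. The RPKM is relative to all reads of its library, so a few very abundant genes lower the values of all the others. For this reason calls were repeated after rescaling 30M by the median ratio of genes at an RPKM of at least 1 in both libraries, and the main counts are given under both scalings.

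The other alternatives were pseudocounts of 0.1 and 1, no minimum RPKM and a minimum of 5, a 4-fold threshold, scaling by a trimmed mean of log ratios (30% of ratios and 5% of abundances trimmed from each end), by the 75th percentile, by totals without the 50 most abundant genes of either library and by TPM, and random thinning of the 30M reads to the Emb135 total. For 7 genes the 2 tables gave different lengths; the RPKM was used as deposited. The calling rule was tested on simulated data over 16174 genes, drawn from the mean read shares and the totals of these libraries. Counting noise of independent reads was the only noise. The rule recovered 100 of 100 genes changed 3-fold and 100 of 100 changed 8-fold, and called 3 of 12103 unchanged genes. The changed genes had a mean RPKM of at least 2 and went up and down in equal numbers. No general shift between the libraries was simulated, so these rates cover counting noise and do not carry over to calls that depend on the scaling. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.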

Results

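Transcript abundance in bovine longissimus muscle was compared between the embryonic stage at 135 days after insemination (Emb135) and the adult stage at 30 months after birth (30M). The series' title places the comparison in a study of transcription during the development of this muscle. Each stage was represented by 1 library from a pool of 3 animals, with 17736812 unique reads for Emb135 and 19970007 for 30M. Every ratio therefore compares 2 libraries and has no replicate check. The counting intervals given with the ratios cover counting error of independent reads only. The ratios also carry differences between animals and between library preparations.

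More genes were detected in the Emb135 library than in the 30M library. Of the 16174 genes with a read in either library, 15522 had at least 1 read in Emb135 and 14853 in 30M, and 14201 had reads in both. At an RPKM of at least 1, which corresponds to 33.8 reads in Emb135 and 38.2 in 30M for a gene of median length, 12125 genes were detected in Emb135 and 11285 in 30M. Of these, 10647 were shared, 1478 reached that level in Emb135 alone and 638 in 30M alone. The shared genes made up 83.4% of those that reached it in either library. The 30M library had the larger depth and the fewer genes. Thinned to the Emb135 total, it had 11281 genes at that level. Thinning equalizes the totals only. The leading genes took a larger share of the 30M reads, which leaves fewer reads for its other genes, and detection was not counted again after rescaling. Whether fewer genes were expressed in 30M is therefore not settled by these counts. At an RPKM of at least 5 the counts were 8486 and 7220. Across the 12763 genes at an RPKM of at least 1 in either library, log2(RPKM + 0.5) correlated between the stages with Pearson's r = 0.75 and Spearman's rho = 0.73; genes are not independent replicates and no p-value is attached.

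Genes read at one stage and missing at the other were few and mostly weakly expressed. In the 30M library 1321 genes of Emb135 had 0 reads, and 516 of them had only 1 or 2 reads in Emb135. Among the 175 that reached an RPKM of at least 1 in Emb135, the median was 63 reads, and against the floor of 3 reads 148 were at least 8-fold higher in Emb135. The gene with the most reads in this set had 2969 in Emb135, which places it at least 1114-fold higher there. In the opposite direction 652 genes of 30M had 0 reads in Emb135. Of the 80 such genes at an RPKM of at least 1 in 30M, 64 were at least 8-fold higher in 30M against the same floor, and the gene with the most reads, 1707, was at least 505-fold higher.

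The 30M library was concentrated in fewer genes. Its 10 most abundant genes by reads held 25.9% of its reads (exact 95% interval 25.90 to 25.94%), against 12.4% for the 10 most abundant of Emb135 (12.42 to 12.45%). Both intervals cover the counting of reads within a library only. They do not measure the uncertainty of the difference between stages. The 100 most abundant held 49.8% of the 30M reads and 37.0% of the Emb135 reads. One gene took 5.55% of all 30M reads and 0.480% of the Emb135 reads. The leading gene of Emb135 took 2.52% there and 0.0724% in 30M. In 30M 102 genes were enough to reach 50% of the reads, in Emb135 243 genes. The effective number of genes, the exponential of the Shannon entropy of the read shares, was 920.0 in 30M and 1948 in Emb135.

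**Figure D1:**
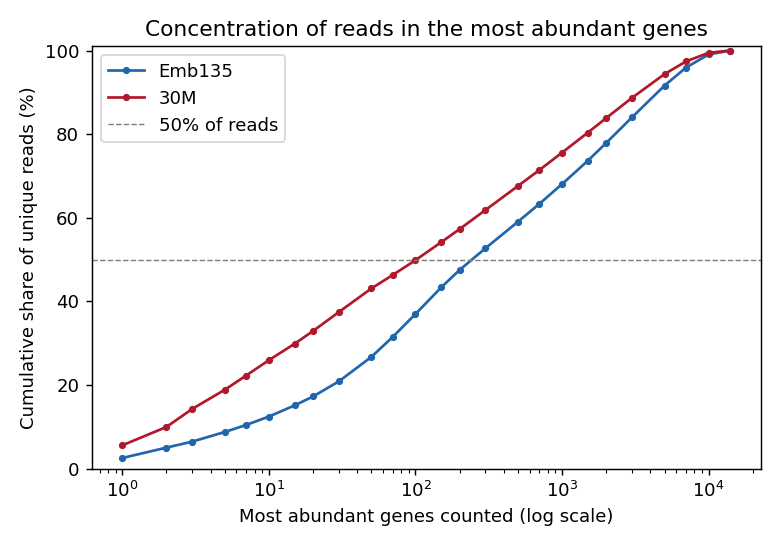
Cumulative share of unique reads (vertical axis, percent) held by the most abundant genes, ranked within each library by reads (horizontal axis, number of genes, log scale), for Emb135 (blue) and 30M (red), 1 pooled library each. The 30M curve reaches the dashed line at 50% with 102 genes and the Emb135 curve with 243 genes.

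The sets of leading genes differed between the stages. Ranked by reads, 36 genes were among the 100 most abundant at both stages, and 2 were among the first 10 at both. Of the 100 leading genes of Emb135, 77 were lower in 30M, 8 were higher and 15 were neither. Of the 100 leading genes of 30M, 65 were higher in 30M, 13 were lower and 22 were neither. A gene chosen for its rank in a library tends to be higher in that library, so these directions are not independent of the choice. With 30M rescaled by the median ratio, 69 of the leading genes of Emb135 were lower and 73 of those of 30M were higher. Ranked by RPKM, which gives short genes more weight, 56 genes were among the 100 most abundant at both stages and 4 among the first 10. By that ranking 78 of the leading genes of Emb135 were lower and 8 higher in 30M, and 45 of the leading genes of 30M were higher and 35 lower. Of the genes ranked by reads, the 100 leading genes of 30M held 21.1% of the reads already in Emb135. The 100 leading genes of Emb135 held 28.3% of the reads in 30M.

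Across all 12763 genes at an RPKM of at least 1, 1665 were higher and 4167 lower in 30M by the rule of size on the RPKM as deposited, and 6931 were neither. The median log2 ratio of these genes was -0.53 (exact 95% interval of the median -0.55 to -0.50), so the middle gene lay below equality on this scale. That interval takes genes as independent and covers no variation between animals or libraries. With 30M rescaled by the median ratio, which raised its values 1.40-fold, 2581 genes were higher and 2714 were lower. The minimum RPKM was applied to the rescaled values, so genes outside the 12763 could enter, and only as higher or neither. This rescaling sets the middle of the genes at an RPKM of at least 1 in both libraries to equality, so the near balance of the counts is built into it and is no result on direction. The lower genes were 71.5% of the calls as deposited. The rescaling raised every 30M value by the same factor, so no higher call could be lost and no lower call gained. That all 1665 genes called higher stayed so, and that the 2714 lower genes were all among the 4167, was thus fixed in advance. At 4-fold or more, 698 genes were higher and 1319 lower as deposited; after rescaling the order turned, with 1046 higher and 902 lower. Which direction held more genes therefore depended on the scaling.

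**Figure D2:**
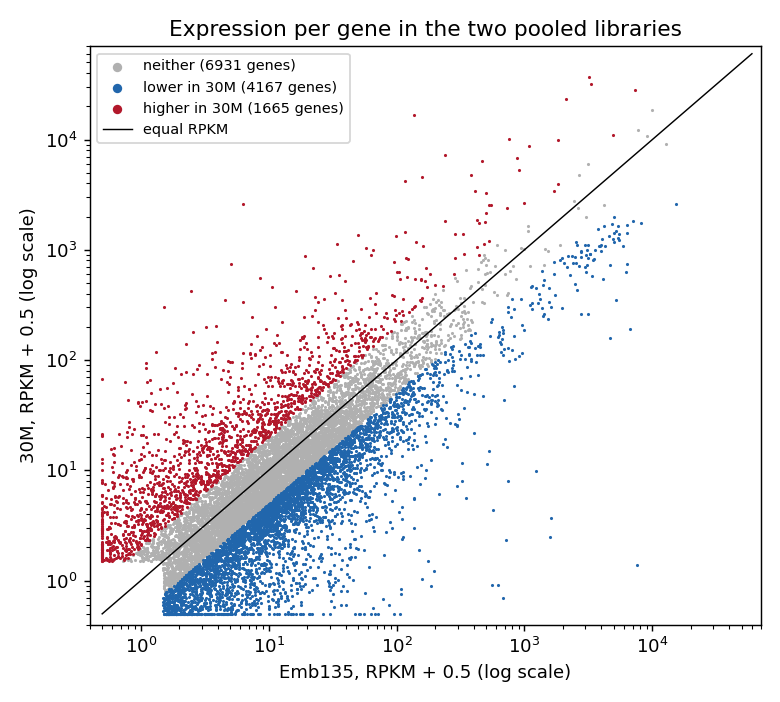
RPKM + 0.5 per gene in Emb135 (horizontal axis, log scale) and 30M (vertical axis, log scale), 1 point per gene for the 12763 genes at an RPKM of at least 1 in either library. Red points are the 1665 genes called higher in 30M, blue points the 4167 called lower and grey points the 6931 called neither; the bulk of the points lies below the line of equal RPKM, and the highest 30M values lie above it.

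The genes called higher held 9.30% of the Emb135 reads and 54.8% of the 30M reads. The genes called lower held 56.6% of the Emb135 reads and 12.7% of the 30M reads. The other genes held 34.1% and 32.5%. These shares are for the calls on the deposited scale. The calls were made from the same reads, so the direction of the shares follows from the choice of genes. Large ratios occurred in both directions: at 16-fold or more, 110 genes were higher and 176 lower in 30M as deposited, and 182 were higher and 143 lower after rescaling. At 64-fold or more, 13 were higher and 31 lower as deposited, and 20 and 28 after rescaling.

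The share of higher and lower genes varied with the abundance of the gene, taken as the mean RPKM of both libraries. As deposited, more genes were lower than higher in each class. Among the 3880 genes at a mean RPKM of 1 to 5, 33.1% were lower and 12.4% higher in 30M, and after rescaling 22.6% were lower and 18.1% higher. Among the 4924 genes at 5 to 20, 31.1% were lower and 10.0% higher, and after rescaling 18.5% and 16.7%. Among the 2653 genes at 20 to 100, 30.2% were lower and 15.5% higher, and after rescaling 18.3% and 22.5%. Among the 525 genes at 100 to 500, 31.6% were lower and 23.0% higher, and after rescaling 22.7% were lower and 32.6% higher. The 189 genes at 500 or more had the lowest median, a log2 ratio of -1.28, with 103 genes lower, 46 higher and 40 neither. In this class the lower genes also outnumbered the higher ones after rescaling, 82 against 60, with a median of -0.80. Under the scaling that raised 30M most, the trimmed mean of log ratios, they were 75 against 62. The class was set by the deposited values and held the same 189 genes under every scaling. Genes that a raised 30M value would bring into it were not counted. After rescaling by the median ratio, its gene models of 800 nt or more were 38 lower and 38 higher. The shorter ones were 44 lower and 22 higher.

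**Figure D3:**
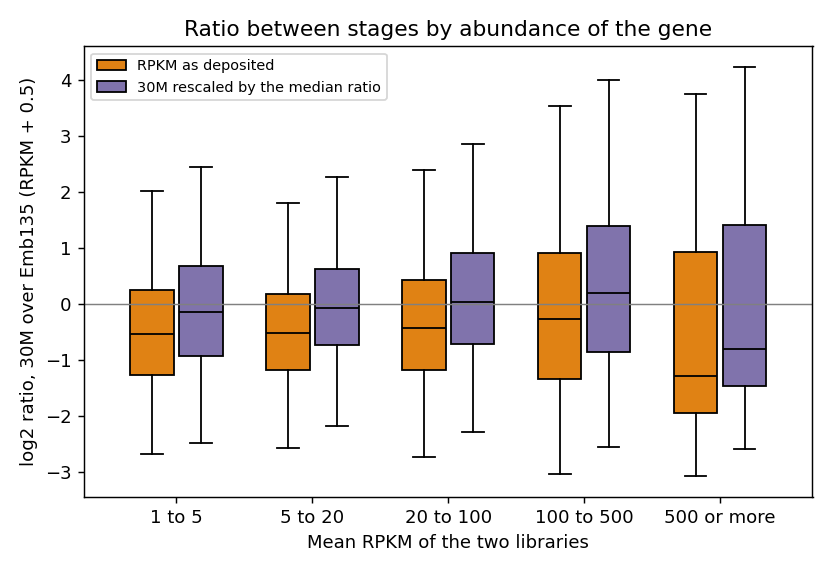
Log2 ratio of 30M over Emb135 on the RPKM + 0.5 scale (vertical axis) for genes grouped by the mean RPKM of both libraries (horizontal axis), as deposited (orange) and with 30M rescaled by the median ratio (purple). Boxes span the quartiles over genes with the median as a line, and whiskers the central part of the genes without the 5% at each end; the median falls to -1.28 as deposited and -0.80 after rescaling in the class at 500 or more.

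On the log2(RPKM + 0.5) scale, which shrinks the ratios of genes with few or 0 reads at a stage, the 2 lowest and the 2 highest ratios among genes with an RPKM of at least 10 at either stage were as follows. The lowest ratio was that of ENSBTAG00000037644, with a gene model of 679 nt, at an RPKM of 7628 in Emb135 (91872 reads) and 0.885 in 30M (12 reads), a log2 ratio of -12.43. Its share of reads was 8620 times as large in Emb135, and the 95% counting interval of the log2 ratio of reads ran from -14.03 to -12.27. The next was ENSBTAG00000009702, with a model of 5934 nt, at an RPKM of 675.0 in Emb135 (71043 reads) and 0.194 in 30M (23 reads), with a counting interval of -12.42 to -11.18. The highest ratio on that scale was that of ENSBTAG00000021685, with a model of 1772 nt, at an RPKM of 5.79 in Emb135 (182 reads) and 2582 in 30M (91382 reads). Its log2 ratio was 8.68, with a counting interval of 8.59 to 9.02. ENSBTAG00000043553, with a model of 1564 nt, was at an RPKM of 1.01 in Emb135 (28 reads) and 303.6 in 30M (9481 reads), with a counting interval of 7.70 to 8.82. Their genome positions are not given in the tables.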

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

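The flags come from the coverage column, which the comparison of expression did not use, and from the listed lengths, which enter it only through the RPKM. The tests were chosen after the values were seen. Neither has a control or a replicate library to set it against.

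The coverage column gave a readout of how much of each gene model was read. Among 8533 genes with enough reads in both libraries for an expected coverage of at least 99%, if reads fell evenly along the model, the median coverage was 97.6% in Emb135 and 97.0% in 30M. Coverage differed by at least 20 percentage points in 59 of them, lower in 30M for 43 and lower in Emb135 for 16. In 48 of the 59 the library with lower coverage also had fewer reads, and there depth and a change in which part of the gene was read cannot be told apart. In the other 11 genes the library with lower coverage had at least as many reads, so a shortage of reads is argued against, and 4 of these had at least 500 reads in both libraries. The gene with the most reads among the 11 was ENSBTAG00000009707, with a model of 1851 nt, 32585 reads in Emb135 and 37395 in 30M; its coverage was 93.8% in Emb135 and 71.0% in 30M while its log2 ratio was 0.03. Of the 11 genes, 10 were called neither higher nor lower, so the expression ratio did not show those 10. Of all genes at an RPKM of at least 1 in either library, 54.3% were neither. The gene with the largest difference in coverage, 93.0% in Emb135 and 45.8% in 30M, was the 1 called. It was higher in 30M, with a log2 ratio of 1.38. A candidate explanation is the use of a different isoform at each stage; reads stacked on a short stretch of the model in 1 library would look alike, and positions along the gene, which would separate these, were not analysed here.

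The 2 tables listed 7 genes with different model lengths, by up to 1.45-fold, so that the RPKM ratio of these genes mixes the length with the expression. With a single length for both libraries, 2 of the 7 were called, as many as on the deposited values.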

How the results depend on the processing

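The alternatives for the counts of genes, the detected genes, the shares and the printed identifiers were fixed before the data were examined; those for the median ratio, for the length-matched genes and for coverage were added afterwards. The fold threshold and the scaling moved the counts. Genes higher in 30M went from 1665 to 2581 with the median ratio, to 2743 with the trimmed mean and to 698 at 4-fold; genes lower went from 4167 to 2714, 2535 and 1319. The lower genes were 48.0% of the calls with the trimmed mean, 54.9% with the 75th percentile, 55.8% with totals without the 50 most abundant genes and 67.5% with TPM. With the other alternatives both counts were within 1.5 times their values. The median log2 ratio of all genes went from -0.53 to -0.57 and -0.48 with pseudocounts of 0.1 and 1, -0.38 with no minimum RPKM, -0.070 with the median ratio, -0.0010 with the trimmed mean, -0.15 with the 75th percentile, -0.17 without the 50 most abundant genes, -0.43 with TPM and -0.45 without the 13 length-matched genes; the median ratio and the trimmed mean are set from the genes' own ratios, so their medians near 0 and near-even counts are built in. Detected genes in 30M fell to 7220 at an RPKM of 5. Ranked by RPKM instead of reads, 56 of the 100 leading genes were shared. As shares of summed RPKM, the 10 leading genes held 12.2% in Emb135 and 28.8% in 30M, and the 100 leading genes 51.4% and 57.4%. The log2 ratios of the 4 printed identifiers were recomputed under 8 alternatives each. Of these 32 values 20 lay outside the counting interval of the ratio of reads, as did the main values of ENSBTAG00000009702 and ENSBTAG00000043553, which the pseudocount shrinks; ratios this large could not change direction under these alternatives. Genes with differing coverage despite as many reads went from 11 to 59 at 10 points and 3 at 30 points. Thinning 30M to the Emb135 total left 1674 genes higher and 4172 lower, of which 1651 and 4106 were called before; this bears on the difference in depth between the libraries, not on what their depth limits. No paired analysis was possible because each stage had 1 library, and no replicate could be left out. The alternatives planned for the gene lists were not run.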

Other observations

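The tests in this part were chosen after the values were seen. Among the genes with the highest RPKM in Emb135 more were lower than higher in 30M, as a choice by the Emb135 value favours. Of the 80 genes with an RPKM of at least 2000 in Emb135, 65 were lower in 30M, 5 were higher and 10 were neither, with a median log2 ratio of -1.82; after rescaling by the median ratio 56 were lower and 9 higher. Of the 106 genes at 500 to 2000, 68 were lower and 14 higher, with a median of -1.51, and 54 and 18 after rescaling. Of the 194 genes at 200 to 500, 91 were lower, 17 higher and 86 neither, with a median of -0.93, and after rescaling 68 were lower and 30 higher.

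Another set was formed by length and abundance. The 13 protein genes of the bovine mitochondrial chromosome in the reference table (assembly ARS-UCD2.0) have 13 different lengths, which 64 genes of the deposited tables share. The most abundant gene at each length, judged by the lower of its 2 values, had an RPKM of at least 491.8 in both libraries. In 10000 random draws of 13 lengths from the tables, 0 had so abundant a gene at all lengths, and the most in a draw was 5. The hypothesis that the length-matched genes are the mitochondrial protein genes would give this result. It was found and tested on the same data, and no identifier was matched. Abundant genes often had short models. At a mean RPKM of at least 500, 94 were under 800 nt and 95 longer, against 522 and 7055 at 5 to 100. How often draws matched for short lengths would reach the result was not tested. The 13 genes held 4.14% of the reads in Emb135 and 10.0% in 30M. Their log2 ratios ran from 0.20 to 2.11 with a median of 1.02, so all 13 were above 0; 7 were called higher and 6 neither, and 10 were called higher after rescaling by the median ratio.

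The excess of genes lower in 30M may come from composition, since the RPKM divides each gene by all reads of its library and the leading genes took a larger share in 30M. Leaving the 50 most abundant genes of either library out of the totals moved the median log2 ratio of all genes from -0.53 to -0.17, and leaving out the 13 length-matched genes moved it to -0.45. Leaving genes out of the totals rescales 30M against Emb135 by 1 factor for all genes, set by the read shares, and the number of 50 genes is a choice. A larger output of the leading genes and a smaller output of all the others cannot be told apart here, because the values are relative to each library's total; the stage itself stays open and untested, since stage and library coincide.

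Gene length was tested as a source of the fall among the most abundant genes. At a mean RPKM of at least 500, the 94 genes with models under 800 nt had a median log2 ratio of -1.43 and the 95 longer ones -0.77. The difference of -0.66 had a 95% bootstrap interval over genes of -1.91 to 0.17, so length and no effect of length cannot be told apart in this class. At a mean RPKM of 5 to 100 the same difference was -0.11 (-0.24 to -0.01). Genes are not independent, and these intervals do not cover variation between animals. In the class at 500 or more, after rescaling by the median ratio, 44 of the shorter genes were lower and 22 higher. Of the longer ones 38 were lower and 38 higher. The medians of the shorter and the longer genes were then -0.95 and -0.29.

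Gene models whose length was a multiple of 3 made up 45.34% of the 16174 genes (exact 95% interval 44.6 to 46.1%), against 33.3% by chance. A part of the models may therefore hold coding sequence alone. The effect of this on their RPKM was not tested. A ratio of reads between the stages does not use the length, while the log2(RPKM + 0.5) ratio of a gene with few reads does. 

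Coverage at matched depth was close between the libraries: genes with 100 to 300 reads had a median coverage of 93.4% in Emb135 and 93.0% in 30M, and the 435 genes that differed by 10 points or more included 59 with as many reads in the library with lower coverage.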
